A study of Lactobacillus acidophilus NCFM with 2 samples.

How the data were processed

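Total RNA of Lactobacillus acidophilus NCFM, a lactic acid bacterium used as a probiotic, was compared on 2 spotted DNA microarray slides. Early log phase cells (OD600 of 0.3) were held for 30 min at 37 °C in MRS, a rich growth broth, with or without 0.5% oxgall, dried ox bile. Both slides carried RNA of oxgall-treated and of untreated cells in opposite dyes: oxgall in Cy5 on slide 1 and in Cy3 on slide 2, with the MRS RNA in the other channel. The labels name the slides as replicates 1 and 2 and describe a pair of slides per experiment with dyes swapped. They do not say that the slides came from separate cultures, so p-values here measure the spread between slides, dye effects included, which may be technical. The series' design describes MRS-grown cells as a common reference, so the MRS RNA is taken as the control and each ratio is tested against 0. Where both slides carried the same MRS RNA, the spread of the control itself is left out.

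The spot intensity and local background of each channel were quantified by the authors in QuantArray 3.0, per the labels. The raw intensity columns are not background-subtracted, per the file headers. The deposited ratio of channel 2 over channel 1 equals the background-subtracted signals' ratio times a constant per slide and was not used in any test. The deposited log2 values of the series table equal the log2 ratio of plainly background-subtracted signals plus a constant per slide, and all run as oxgall over MRS by the labels. The table's log2 values of slide 2 have the opposite sign of the deposited sample values. How the authors chose those constants is not given in the sources used here. The medians of the deposited log2 ratios were -0.16 on slide 1 and -0.35 on slide 2, and 12 spots of slide 1 were empty. No column of per-sample values was left unmapped. An annotation of the array by locus is not used here.

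Each of 1895 probes was spotted 3 times on a slide, giving 5685 spots. The files name probes by a short gene name or product, with 1021 distinct names, and 853 probes carry a name found once. A probe whose name repeats is given with the first of its 3 feature numbers. In all, 512 probes are named only as hypothetical or unknown, some of them with a name found once. A further 1 probe whose spots carry different names was given the majority name.

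From the raw intensities, background was corrected with normexp and an offset of 50, log2 ratios were normalized by loess within each slide, the sign was turned so that positive means higher with oxgall, and the 3 spots of a probe were averaged. Both slides entered an intercept-only limma model (limma 3.58.1, R 4.3.3) with empirical Bayes moderation. Tests were two-sided, with the Benjamini-Hochberg adjusted p under 0.05 as threshold. Probes at least 2-fold apart in the same direction on both slides were also counted, which needs no test. The number of slides limits the precision. Tested on simulated slides with real intensities and 200 planted changes among 1895 probes, the steps recovered 100% of log2 changes of 3 in either direction. Of planted changes of 2, they recovered 81.8% of the increases and 88.2% of the decreases, and of changes of 1, 18.2% in either direction. Among 1695 unchanged probes, 17 were called, out of 153 calls in all, a larger share than the threshold of 0.05 aims at. The simulated probes varied independently, with spread drawn from the fitted prior, and carried no dye bias, signal floor or saturation. These rates may therefore not hold for the real slides, where 33 probes passed and none with a log2 ratio under 2.03 in size.

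Themes of the gene lists were fixed before the data were examined. The spelling by which members are found was adapted to the files' names before any ratio was looked at. This gave 24 lists. Another 2 lists, a bile operon and bile tolerance transporters, were defined by locus tag and are not analysed here. For each list, the count past the threshold is given over all probes and adjusted over the list alone. The list median is placed among 10000 random lists of the same size matched on intensity in 10 classes, as a description of these slides. If probes varied independently, chance would place 1.2 of 24 lists outside the central 95%. Neighbouring probes vary together, so more may fall outside by chance, and each list was also set against its 1894 shifts along the file order, which keep neighbours together.

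Genes were named by a rule fixed before the data were examined: the 15 highest and 15 lowest among probes past the threshold with the same sign in every spot, filled to 10 in a direction with fewer calls, both bile salt hydrolases, and up to 4 members of other lists by size. Where a list held no call and lay inside the central 95% of random lists, 1 member was kept, a narrowing made after values were seen. Members of runs of 5 or more neighbouring probes were added after their values were seen.

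Alternatives fixed beforehand were median centring in place of loess, plain or no background subtraction, the deposited log2 ratios, the median of spots, leaving out the dimmest 25% of probes, each slide alone, all spots with slide as block or with a dye term, a trended and robust prior, Bonferroni adjustment, folds of 1.5 and 4, and unmatched random lists. Plain subtraction with median centring, leaving out saturated spots, and the shifts of lists along the file order were added after seeing the data. With median centring, the deposited ratios, and plain subtraction with median centring, the prior degrees of freedom were estimated as infinite. Every probe then has the same error. The calls in those settings follow the size of the mean and do not measure a probe's own spread between slides. Figures were drawn with matplotlib 3.10.9.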

Results

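The series measured how Lactobacillus acidophilus NCFM responds to bile, by comparing early log phase cells after 30 min in MRS broth with 0.5% oxgall against cells in MRS alone. There was 1 group of 2 slides with dyes swapped. On slide 1 the median raw intensity was 1655 for MRS (Cy3) and 1429 for oxgall (Cy5), and 77.2% and 76.1% of spots lay more than 2 background SDs above background. Slide 2 was brighter, with medians of 6768 for oxgall (Cy3) and 5028 for MRS (Cy5), and 100% of spots passed that mark in both channels. Its dimmest oxgall spot read 4333 over a median local background of 1324, and 78 oxgall and 103 MRS spots were at the scanner ceiling. No spot of slide 1 was.

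Bile raised probes for the stress-named membrane protein pspC, a multidrug resistance protein, the co-chaperonin groES, the Clp ATPase clpE, the protease htrA, and the enzymes pck, pgmB, maltose phosphorylase and poxB. The highest was pspC, named for phage shock protein C, at a log2 ratio of oxgall over MRS of 4.31 ± 0.51 (SD, n = 2 slides), 19.9-fold, with a limma adjusted p of 0.00287. The multidrug resistance protein at feature 4144, of the class that exports toxic compounds, rose 12.2-fold (log2 3.61 ± 0.38, SD, n = 2, adjusted p 0.00418). A hypothetical protein beside it at feature 4147 rose 15.9-fold (log2 3.99 ± 0.79, SD, n = 2). The lowest was a probe of lysin, a name given to cell wall hydrolases, at feature 3283 and log2 -2.74 ± 0.85 (SD, n = 2, adjusted p 0.0192). Of 1895 probes, 30 were higher and 3 lower past the threshold, each with the same sign in all spots of both slides. This balance was not kept with median centring (75 higher and 88 lower) or with all spots and slide as block (75 and 49).

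Several of the other probes that rose belong to protein quality control. The co-chaperonin groES rose by a log2 of 2.81 ± 0.08, and htrA, a membrane serine protease that degrades damaged proteins, by 2.77 ± 0.02 (SD, n = 2 each). The 2 probes named clpE, for a Clp ATPase, rose by 2.47 ± 0.93 at feature 1828 and 2.51 ± 0.97 at feature 5479. The name does not show whether they stand for the same gene. On slide 2, 2 of the 3 spots at feature 1828 were at the scanner ceiling, and without them the value was 2.60 ± 0.75 (SD, n = 2, adjusted p 0.0177). The partner of groES, groEL, had a log2 ratio of 2.40 ± 1.79 and did not pass (adjusted p 0.0691), with a value of 3.67 on slide 1 and 1.14 on slide 2. It passed with median centring (2.29, limma adjusted p 0.000512), with slides at 3.18 and 1.41. That test gives every probe the same error, so this spread did not count.

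The gene pck, for phosphoenolpyruvate carboxykinase, rose 9.26-fold (log2 3.21 ± 0.03, SD, n = 2, adjusted p 0.00739). Maltose phosphorylase rose by a log2 of 2.37 ± 0.24, and pgmB, the beta-phosphoglucomutase that takes up its product, by 2.61 ± 0.10 (SD, n = 2 each). The pyruvate oxidase gene poxB rose by 2.38 ± 0.20, and a sugar transporter at feature 127 by 2.88 ± 0.996 (SD, n = 2 each).

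Among membrane and other proteins, the probe of pacL, a cation-transporting ATPase, at feature 4825 rose by a log2 of 3.10 ± 0.998 and a membrane protein at feature 3226 by 2.81 ± 0.71. All 3 spots of that membrane protein were at the scanner ceiling on slide 2, which leaves only slide 1, at 2.31, as a value free of saturation, so the probe has no replicate check there. The myosin-crossreactive antigen, of a family with fatty acid hydratases, rose by 3.01 ± 0.63, and arsC, named for arsenate reductase, by 2.53 ± 0.01 (SD, n = 2 each). The other 2 probes named pacL did not pass. An unknown protein at feature 46 also passed at 3.76 ± 2.77, but its slides read 1.80 and 5.72.

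The other 3 probes named lysin did not pass. Beside lysin at feature 3283, the lower probes past the threshold were an amino acid permease at feature 2857, at a log2 ratio of -2.07 ± 0.06, and radA, a DNA repair gene, at -2.03 ± 0.36 (SD, n = 2 each, adjusted p 0.0397 and 0.0443). The next lowest probes with the same sign in every spot did not pass: glmS, an enzyme of amino sugar synthesis, at -1.93 ± 0.54, the exonuclease gene recJ at -1.92 ± 0.22, the cysteine desulfurase gene nifS at -1.80 ± 0.11, pth, for peptidyl-tRNA hydrolase, at -1.78 ± 0.17, the excision repair gene uvrA at -1.78 ± 0.24, trcF at -1.75 ± 0.09 and dapF, of lysine and cell wall precursor synthesis, at -1.74 ± 0.41. With median centring these 7 probes were lower past the threshold, with limma adjusted p from 0.000204 (recJ) to 0.00449 (glmS). That test takes no account of a probe's own spread between slides.

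**Figure D1:**
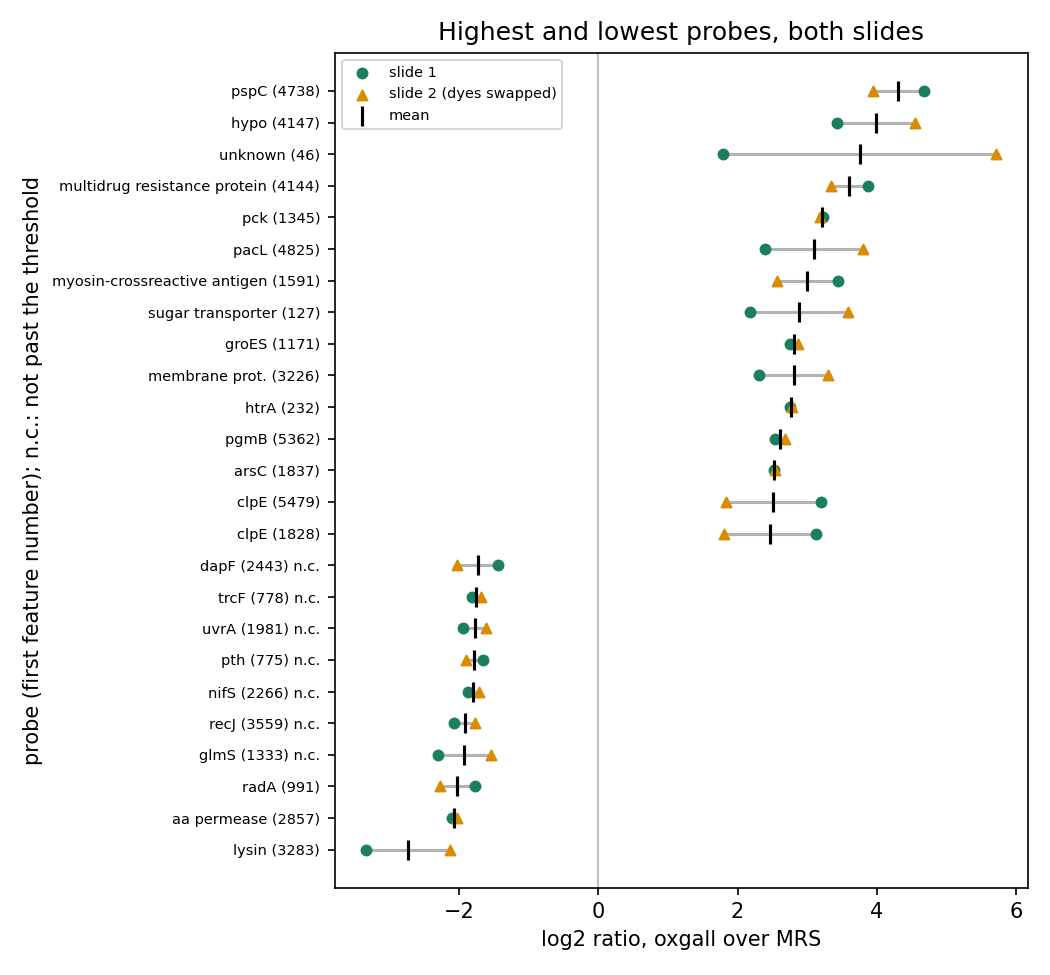
Log2 ratio of oxgall over MRS on slide 1 (circles) and slide 2 (triangles), with their mean (bars), for the highest 15 and lowest 10 probes, named with their first feature number. The highest mean is that of pspC at 4.31 and the lowest that of lysin at feature 3283 at -2.74, and the slides lie far apart for the unknown protein at feature 46.

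The slides were related across probes, with a Pearson r of 0.42 and a Spearman rho of 0.35 over genes, which are not independent replicates. The sign was the same on both slides for 1178 of 1895 probes (62.2%). At least 2-fold differences on both slides were seen for 69 probes higher and 33 lower with oxgall, among them all 33 that passed the test, and 5 probes were at least 2-fold in opposite directions. The smallest log2 ratio that passed was 2.03 in size. At an unadjusted p under 0.05 there were 239 probes, 130 higher and 109 lower.

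The balance between higher and lower probes depended on the normalization and on the error model. Of the calls, 90.9% were higher in the test of slide means after loess, 46.0% with median centring of each slide in place of loess, and, after loess, 60.5% with all spots and slide as block and 50.7% with all spots and a dye term. All 33 probes stayed past the threshold with median centring, where the test goes by the size of the mean alone. With the signals not corrected for background, limma gave 0 calls, with 220 probes at an unadjusted p under 0.05.

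**Figure D2:**
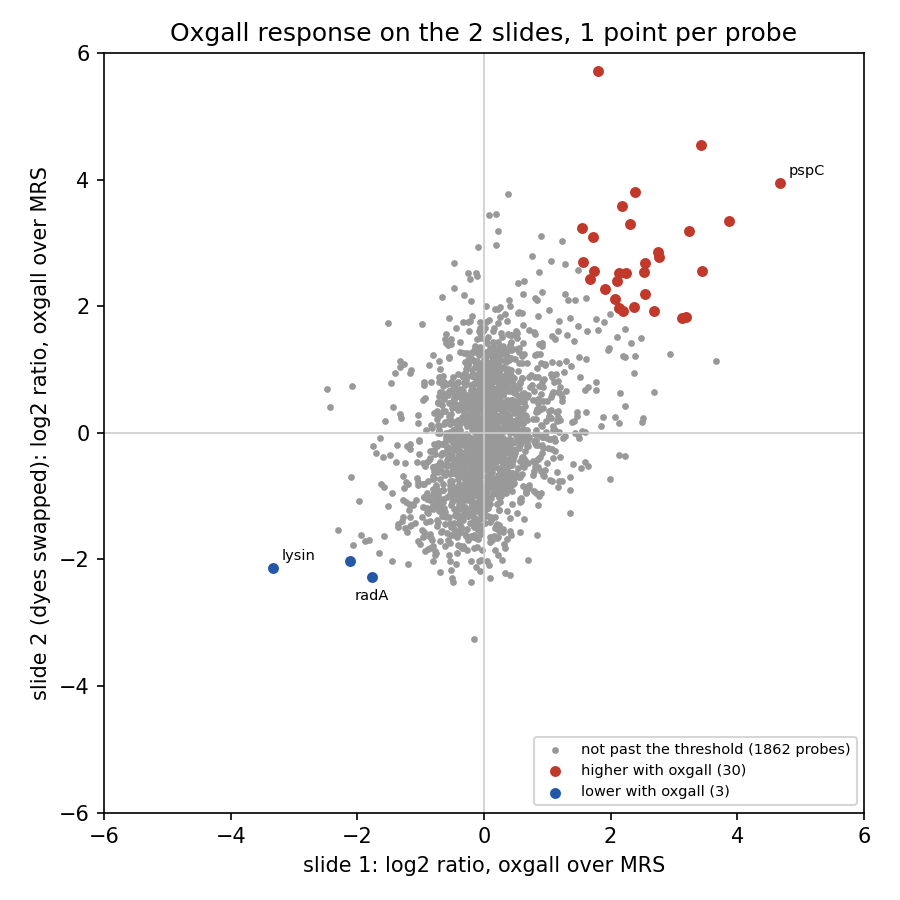
Log2 ratio of oxgall over MRS on slide 1 (x axis) against slide 2 with dyes swapped (y axis), 1 point per probe, with the 30 higher and 3 lower probes past the threshold in colour. Called probes lie at least 2-fold from 0 on both slides, and the remaining points scatter with a Pearson r of 0.42 over all 1895 probes.

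Among the gene lists, chaperones and Clp proteases held the most calls: 3 of 17 probes rose, 4 adjusted over the list alone, and 14 did not pass. The calls were groES and the probes named clpE. The list's median of probe means was 0.82 (log2), at percentile 100 of random lists, above its medians of 0.56 on slide 1 and 0.18 on slide 2. Of the members, 8 were positive and 5 negative on both slides. On slide 2 alone the percentile was 93.6. With the deposited ratios, made with another background correction, no loess and another scaling, the median was -0.01 at percentile 99.995. For beta-galactosidase and lactose use, limma called 0 of 16 probes over all probes and 4 higher adjusted over the list alone, with 6 higher and 1 lower at an unadjusted p under 0.05. The members galK, for galactokinase, at 2.09 ± 1.19, lacL at 1.87 ± 0.64, galT at 1.66 ± 1.44 and lacM at 1.66 ± 0.45 led it (SD, n = 2 each). The list median was 0.92 at percentile 100, and 96.8 on slide 2 alone, with medians of 0.76 on slide 1 and 0.53 on slide 2.

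Ribosomal proteins had a median of 0.40 over 52 probes at percentile 100, with 19 probes positive and 6 negative on both slides. Their medians were 0.26 on slide 1 and 0.19 on slide 2. The list median of 0.40 turned to -0.35 with the deposited ratios and -0.10 with plain subtraction and median centring, while the percentile was 99.97 and 99.95. None of them passed (0 calls by limma over all probes and 0 over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05). Their leading members rpmA, at 1.82 ± 2.31, and rplU, at 1.45 ± 1.30, differed widely between slides (SD, n = 2 each). Peptidoglycan and teichoic acid genes had a median of 0.32 over 35 probes at percentile 99.3, which turned to -0.43 and -0.18 under the same settings, at percentiles of 99.1 and 98.8. By limma the list held 0 calls over all probes and 2 higher adjusted over the list alone, the same number as at an unadjusted p under 0.05, and its members ddl, for D-alanine ligase, and tagA, of teichoic acid synthesis, stood at 2.03 ± 0.77 and 1.71 ± 0.13.

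At the lower end, purine and pyrimidine biosynthesis had a median of -0.54 over 25 probes, at percentile 0.12, with purQ at -1.40 ± 1.27, purC at -1.38 ± 0.53 and purA at -1.31 ± 0.22 (SD, n = 2 each). Aminoacyl-tRNA synthetases, which charge tRNA for translation, had a median of -0.44 over 26 probes at percentile 0.26, with the probe glurs at -1.25 ± 0.24 and argS at -1.14 ± 0.85. Both lists held 0 calls by limma, over all probes and over the list alone, and at an unadjusted p under 0.05 they held 6 and 3 lower probes and 0 higher. With median centring, 5 purine and pyrimidine probes and 4 synthetase probes were lower past the threshold. Exopolysaccharide genes had a median of -0.45 over 26 probes at percentile 0.56, also with 0 calls by limma on either adjustment, and 2 higher and 2 lower at an unadjusted p under 0.05. Their members went both ways, with a galactosyltransferase at feature 1486 at 1.38 ± 1.07 and a glycosyl transferase at feature 4060 at -1.07 ± 1.12, and the percentile lay inside the central 95% on slide 1 alone (22.6), with median centring (3.06, with 2 lower calls), with the deposited ratios (8.15) and with plain subtraction and median centring (9.51).

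Bile salt hydrolases, which split conjugated bile acids, did not pass: bshA stood at 0.60 ± 0.61 and bshB at 0.03 ± 0.52 (SD, n = 2 each, adjusted p 0.592 and 0.981), and the sign of bshB turned with the processing. With 0 calls by limma and 0 at an unadjusted p under 0.05, the pair had a list median of 0.31 at percentile 75.2. Multidrug efflux held 1 higher call, the multidrug resistance protein, among 17 probes, with a median of -0.16 at percentile 16.8. A multidrug transporter at feature 4648 stood at -0.94 ± 0.54 and a daunorubicin resistance protein at -0.95 ± 0.30, neither past the threshold. Two-component systems, sensor and regulator pairs, held 0 calls by limma among 19 probes, with 3 higher and 2 lower adjusted over the list alone and 5 and 2 at an unadjusted p under 0.05, at a median of -0.21 and percentile 15.6. The percentile was 81.4 with median centring, 96.5 with the deposited ratios, 98.1 with plain subtraction and median centring and 96.1 on slide 1 alone, so the list has no settled place.

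DNA repair held 1 lower call, radA, among 26 probes, and 3 adjusted over the list alone, at a median of -0.17 and percentile 17.3, with uvrB at -1.22 ± 0.58. Amino acid transport held 1 lower call, the permease at feature 2857, among 25 probes, at a median of 0.02 and percentile 70.8, while glnP at feature 1666 and glnM stood at 1.14 ± 0.05 and 1.11 ± 0.21. Redox and oxidative stress held 1 higher call, poxB, among 12 probes, at a median of -0.15 and percentile 20.4, with an NADH dehydrogenase at feature 4645 at -1.44 ± 1.06. Glycogen and starch metabolism held 1 higher call, maltose phosphorylase, among 9 probes, at a median of -0.03 and percentile 51.3, with neopullulanase at 0.82 ± 0.15 and glgC at -0.55 ± 0.57. With median centring, DNA repair held 4 lower calls, amino acid transport 2 lower, two-component systems 2 lower, chaperones 4 higher, lactose use 1 higher, and glycogen and starch metabolism 1 higher. Multidrug efflux, redox, and peptidoglycan genes then held 1 higher and 1 lower call each.

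The remaining 10 lists, with 197 probes, held 0 calls by limma, over all probes and adjusted over the list alone, with 13 higher and 6 lower at an unadjusted p under 0.05, and lay inside the central 95% of random lists. With median centring they held 5 higher and 5 lower calls: 2 higher for sugar PTS, 2 higher and 2 lower for surface and adhesion proteins, 1 higher for glycolysis and lactate formation, 2 lower for cell division and 1 lower for transposases. Sugar PTS transporters were at percentile 95.3 (median 0.26, 31 probes), with the mannose transporter gene manM at 1.47 ± 0.41. This list lay above the central 95% on slide 2 alone (98.9), slide 1 alone (99.7) and with median centring (97.8). It also did with plain subtraction (98.5) and without the dimmest 25% of probes (97.8). It lay inside with, among others, the median of spots (90.1), the deposited ratios (91.4) and plain subtraction with median centring (92.8). F1F0 ATP synthase was at percentile 80.4 (median 0.20, 8 probes), fatty acid biosynthesis at 77.1 (median 0.23, 4 probes) and glycolysis and lactate formation at 76.8 (median 0.11, 19 probes). Transposases were at 67.6 (median 0.08, 11 probes), bacteriocin genes at 61.2 (median 0.09, 6 probes) and surface and adhesion proteins at 54.1 (median 0.02, 32 probes). RNA polymerase and sigma factors were at 26.3 (median -0.08, 12 probes), peptide uptake and peptidases at 24.3 (median -0.06, 55 probes) and cell division at 8.78 (median -0.23, 19 probes). No direction is read from the medians of lists inside the central 95%. Mean and median differed in sign for two-component systems (mean 0.05), multidrug efflux (0.01), redox and oxidative stress (0.06), glycogen and starch metabolism (0.22), bacteriocin genes (-0.08) and transposases (-0.09).

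**Figure D3:**
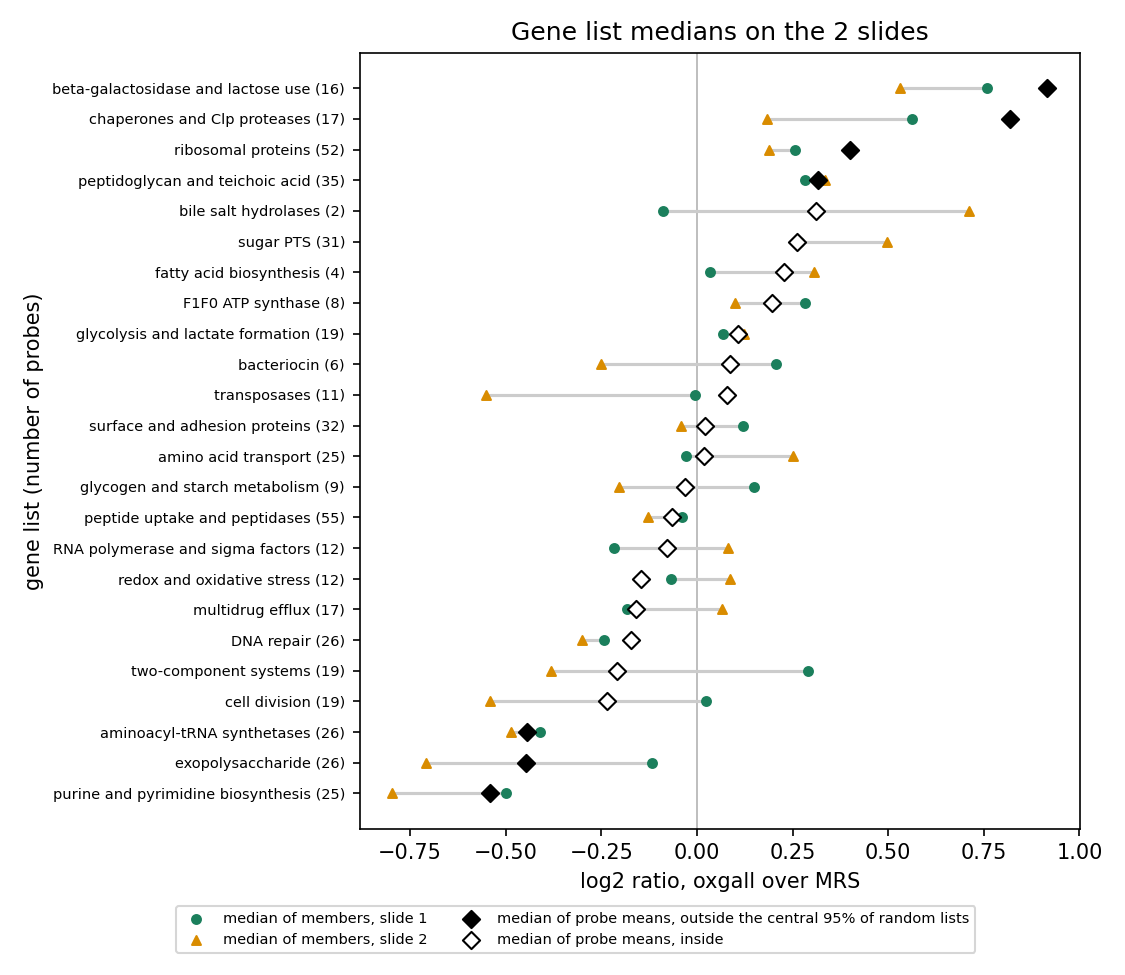
Median log2 ratio of oxgall over MRS of the 24 gene lists, with the medians on slide 1 (circles) and slide 2 (triangles) and the median of probe means (diamonds, filled outside the central 95% of random lists). Lactose use (0.92) and chaperones (0.82) have the highest medians of probe means and purine and pyrimidine biosynthesis (-0.54) the lowest. The chaperone medians were 0.56 on slide 1 and 0.18 on slide 2. With the deposited ratios the chaperone median was -0.01, at percentile 99.995.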

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

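Plain subtraction with median centring, leaving out saturated spots and shifting lists along the file order were chosen after seeing the data. The deposited ratios differ from plain subtraction with median centring only by a constant per slide, their medians of -0.16 on slide 1 and -0.35 on slide 2. Differences between that pair of settings, in counts, list medians and signs, therefore come from this offset. The cause of the other differences was not tested. Counts past the threshold, 30 higher and 3 lower, became 75 and 88 with median centring, 7 and 0 with plain background subtraction, 0 and 0 with no background correction, and 48 and 273 with the deposited log2 ratios. They were 65 and 14 with the median of spots, 167 and 180 with plain subtraction and median centring, 75 and 49 with all spots and slide as block, 557 and 541 with all spots and a dye term, 13 and 5 with a trended and robust prior, and 4 and 0 with Bonferroni. The dye term leaves error within slides only. Without the dimmest 25%, 5 were lower. Leaving out saturated spots gave 32 and 4. For the membrane protein at feature 3226 this leaves slide 1 alone, at 2.31 against 2.81 with both slides, so its lost call reflects the dropped slide. Calls shared with the 33 were 33 with median centring, 33 with the median of spots, 24 with the deposited ratios, 16 with the trended and robust prior and 7 with plain subtraction. Plain subtraction gave 222 probes at an unadjusted p under 0.05.

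Probes at least 2-fold on both slides, 69 higher and 33 lower, had 96 lower with median centring, 19 lower with plain subtraction, 41 higher and 14 lower with no background correction, 197 lower with the deposited ratios, and 149 and 114 with plain subtraction and median centring. At 1.5-fold there were 135 and 125, and at 4-fold 17 and 2. A single slide, a value with no test, gave 150 to 277 higher and 76 to 297 lower. Lists outside the central 95% of random lists, 4 above and 3 below, numbered 3 to 5 above and 2 to 3 below in every alternative run. Against shifts along the file order the same 7 lists lay outside, with ribosomal proteins and peptidoglycan genes at percentile 97.99.

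Under the deposited ratios the medians of chaperones, ribosomal proteins and peptidoglycan genes turned to -0.0072, -0.35 and -0.43, and with plain subtraction and median centring those of the last pair to -0.10 and -0.18. The percentiles of these lists stayed above the central 95% in both settings. Among 25 named probes past the threshold, none turned sign in any alternative. All had the same sign in every spot and a mean of at least 2.03 in size. No turn was therefore possible in alternatives that reuse the same normalized spot values, and the lack of turns there is no support. The call was lost for 25 with no background correction, 21 with Bonferroni, 18 with plain subtraction, 9 with the trended and robust prior, 3 with the deposited ratios, and 1 each with slide as block, plain subtraction and median centring, and without saturated spots. Among 62 others, signs turned under the deposited ratios for rpsF (-0.010), fabG (-0.18), the ATP synthase subunit e (-0.26), pbp-2B (-0.18), rpoZ (-0.22) and plnG (0.18), and with plain subtraction and median centring for that subunit (-0.0026) and plnG (0.43). The value of bshB turned to -0.42 with median centring, -0.082 with plain subtraction, -0.080 with no background correction, -0.60 with the deposited ratios, -0.016 with the median of spots and -0.35 with plain subtraction and median centring. Loess within sub-arrays was not run, since the files give no spot positions. On slide 1, 76.1% of oxgall and 77.2% of MRS spots stood clear of background, which limits dim probes. On slide 2, 100% of spots did, but the dimmest oxgall spot read 4333 against an oxgall median of 6768. The median local background there was 1324, so standing clear of it does not show that a dim probe was detected. Dim probes are thus limited on slide 2 too.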

Other observations

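The test of dye bias was chosen after the slopes had been seen, and runs of neighbouring probes were looked for after the values of single probes had been seen. Probes that follow each other in the files' order often responded together. There were 13 runs of at least 3 neighbouring probes with means of at least 2-fold and the same sign on both slides, 10 higher and 3 lower with oxgall, holding 48 probes, while shuffled orders gave a mean of 0.822 runs and at most 5 in 1000 shuffles. The longest held 7 probes over features 4096 to 4116, with a mean log2 ratio of 1.87: a transporter, a histidine kinase and a response regulator, a conserved hypothetical protein, a pair of dihydroxyacetone kinase probes and glpF, the glycerol facilitator. In that run the transporter at feature 4096 (2.05 ± 0.12, SD, n = 2, as for the values that follow) passed the threshold. So did the dihydroxyacetone kinase at feature 4108 (2.15 ± 0.58) and glpF at feature 4114 (2.13 ± 0.80). The histidine kinase at feature 4099 did not (1.71 ± 0.69, limma adjusted p 0.0969). Nor did the response regulator at feature 4102 (1.80 ± 0.83, adjusted p 0.0891). The conserved hypothetical protein at feature 4105 (1.94 ± 0.41, adjusted p 0.0558) also did not pass. The same held for the dihydroxyacetone kinase at feature 4111 (1.30 ± 0.32, adjusted p 0.220). The other probe named glpF, outside the run, did not pass. A run of 5 probes over features 4138 to 4152 had a mean of 2.79 and held a regulator, a putative pseudogene, the multidrug resistance protein and a pair of hypothetical proteins.

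Smaller higher runs held galM, galT and galK with a surface layer protein probe (mean log2 ratio 1.56, 4 probes), the mannose transporter genes manX, manM and manN (1.40, 3 probes), the chaperone operon genes dnaK, grpE and hrcA (1.29, 3 probes), and a pair of fibrinogen-binding protein probes with an unknown protein (1.19, 3 probes). The highest of the smaller runs held fructokinase with conserved hypothetical, unknown and hypothetical proteins (2.02, 4 probes). The rest held rpmA and rplU with an uncharacterized protein (1.79, 3 probes), ldhD, exoA and gadC (1.28, 3 probes), and rnh1, a conserved hypothetical protein and epsV (1.21, 3 probes). Of the lower runs, 1 held potA, potB, potC and potD, named for polyamine transport, at a mean of -1.23 over 4 probes, and another held radA between dUTPase and glurs at -1.49 over 3 probes. The last held a deoxyribonuclease, an unknown protein and a transcriptional regulator at -1.26 over 3 probes. These means are not tests.

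The log2 ratio of a probe on either slide was correlated with that of its neighbour on the other slide, with a cross-slide r of 0.203 over 1894 neighbour pairs. The highest of 10000 shuffled orders matched on intensity reached 0.0683 (permutation p 1e-04, the smallest these shuffles can give). A pattern within a single slide, or a position effect of the dyes, would by itself leave this value near or below 0. The value of 0.203 argues against either as the sole source. A part from single slides is not excluded, since neighbours on the same slide correlated at 0.465 on slide 1 and 0.260 on slide 2. Neighbours that share a name do not account for the cross-slide value, since r was 0.200 over 1746 pairs of neighbours with different names. Those pairs still include neighbours whose differing names may stand for the same gene, such as Aminopeptidase G PepG and pepG. A part from such pairs is not excluded. Shared transcripts of neighbouring genes may account for part of it, as a hypothesis. The value of r fell with distance, but not steadily: it was 0.0626 at 5 probes, 0.0513 at 7 and 0.0873 at 10. At 20 probes it was 0.0496 and at 50 it was 0.0083. The value at 10 probes was still above the shuffled orders, and transcript units and gene coordinates are not used here.

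Before loess, bright probes stood lower with oxgall on both slides, with slopes of the log2 ratio of -0.132 ± 0.0096 (SE) per log2 of intensity on slide 1 and -0.196 ± 0.012 (SE) on slide 2. Dye bias would give the Cy5 over Cy3 ratio slopes of the same sign, and the slope was 0.196 on slide 2 against -0.132 on slide 1. Saturation is argued against by the slope of -0.223 on slide 2 without saturated spots. A signal floor in the oxgall channel that background correction did not remove remains a candidate for the fall among dimmer probes only. Among the brightest 25%, where such a floor weighs little, the slopes were 0.162 ± 0.043 (SE) on slide 1 and 0.439 ± 0.051 on slide 2. Without saturated spots the latter was 0.396 ± 0.058. A floor alone would leave these slopes near 0, so it does not account for the rise. A response of abundant transcripts to bile stays open, as untested.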
